A study of Homo sapiens with 11 samples.

How the data were processed

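The series holds 11 samples of 3 cell lines: 3 Hi-C libraries, 1 each of DMS153, H209 and MRC5, and 8 RNA-seq libraries, 3 of DMS153, 2 of H209 and 3 of MRC5. The titles of the 3 DMS153 RNA libraries write DM153 and their cell line field DMS153, and they were taken as DMS153, which was not tested. The RNA labels repeat the wet-lab text of the Hi-C samples, so the selection, the strand and the depth of the RNA libraries are not given in the sources used here. Genes that overlap or run antisense to one another can therefore share reads. The submitters' processing notes name Bowtie2, TopHat2 2.1.0, Cufflinks 2.2.0, HOMER 4.8 and the human assembly hg19.

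Per the file headers, each RNA table gives a gene identifier, a symbol, a locus, an FPKM value with the bounds of its confidence interval and a status for each gene, and the values were used as deposited, in FPKM. FPKM is scaled by the mapped fragments of a library, so the level of a gene depends on what else the library holds. Most of the microRNA loci that hold a large share of the summed FPKM in DMS153 are short, so their share of reads is lower than their share of FPKM. The highest of them, MIR144, spans 895 bp. The files hold no counts. The depth of each library relative to MRC5 replicate 1 was estimated as the most frequent ratio of low values of the same genes between the libraries, and the precision of single values was read from the deposited intervals. In 163 genes, 93 of them tested, at least 1 library carried a failed status. Their values were kept as deposited, many of them 0, and a run without those genes was an alternative. Genes listed at 0 in a whole group got no fold change in the text, because mitochondrial genes that every cell uses were also listed at 0 in some libraries. Medians of lists still include such genes, and their fitted change depends on the pseudocount.

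The Hi-C tables have no header. Each line gives the chromosome, the start and the end of a domain and, in 1 further column, a deposited score whose meaning and caller settings are not stated, so the score was used only to rank domains in an alternative. Starts and ends lie on a 20 kb grid of hg19. Domain ends within 20 kb of one another were merged into 1 boundary. A boundary of one line was called shared when it lay within 40 kb of a boundary of the other, gained when only the carcinoma line had it and lost when only MRC5 had it. Domains were called conserved at a reciprocal overlap of at least 80%. Shares were set against 1000 circular shifts of the boundaries along each chromosome, of at least 1 Mb, which keep their spacing; the smallest p these can give is 0.001. With 1 library per line, shifts compare these libraries and not the lines.

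RNA was analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 19066 in all. All 8 libraries entered 1 fit with a mean per line and 5 residual degrees of freedom, because H209 has only 2 libraries, and eBayes was used with a trend. The 3 comparisons were DMS153 against MRC5, H209 against MRC5 and DMS153 against H209, each 2-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested and an absolute log2 fold change of at least 1. Of the called genes, 9557, 9137 and 5132 had no overlap between the libraries of the groups in these comparisons. The call itself favours such separation, so these counts add no separate support. Chance gives 10% for 3 against 3 libraries and 20% for 3 against 2, but over all genes and not over called ones.

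Gene lists, comparisons, tests and most alternatives were fixed before the data were examined. The 41 lists cover lineage, cell cycle, chromatin, stress, metabolism, immunity, HOX and protocadherin clusters and markers of other cell types, and 39 had the 3 tested members needed. Lists and the 41 chromosome arms with at least 20 tested genes were tested with camera, which compares a set with all other genes, at a preset correlation of 0.01 between genes, adjusted per comparison. camera was repeated with an estimated correlation, and fry, which tests whether the genes of a set move on balance one way, was computed beside it. Arms were assigned from hg19 centromeres, without the Y chromosome.

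The genes named in the text follow a rule set in advance. They are the 8 highest and 8 lowest called fold changes per comparison among genes with no overlap between libraries and a mean of at least 5 FPKM in the higher group, without unnamed clones, small RNA, mitochondrial and Y-linked genes. They further include 27 core genes whatever their result (24 of them shown), up to 2 called members of each list with the largest rise and 2 with the largest fall, and genes that begin or end the 5 longest runs of adjacent genes called alike inside a domain. Core genes are also the ones whose domains are given. Genes named outside this rule are the mitochondrial genes with a failed status, the locus of MIR10B, and the marker and microRNA genes of the closing section, which were chosen after their values were seen.

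Genes higher, lower or called in either direction against MRC5 were compared with other tested genes for a locus within 40 kb of a gained, lost or shared boundary, which makes 18 tests adjusted together. Adjacent tested genes at most 500 kb apart were compared within bins of gap length by the absolute difference of their log2 fold changes, in 4 tests. Domain work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

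The gene calls, boundary sharing, conserved domains, boundary odds and adjacent genes were tested on simulated data. No such result is given for the tests of lists and arms. Among 19066 genes, 200 changed ones were planted at a mean level above 2 FPKM, so the recovery of lower genes was not covered. All planted genes changed by 1.5 log2 units or more were called, and 49.02%, 47.1% and 49.02% of those changed by exactly 1. Of 18866 unchanged genes, 2, 3 and 3 were called. Planted boundary sharing of 0%, 50% and 100% gave 13.5%, 56.5% and 100%, with 13.7% to 13.8% under shifts. A planted log2 odds ratio of 0.5 gave 0.45 and one of 0 gave 0.0344. Adjacent genes with a planted domain effect of SD 1 gave a difference of -0.35, and with none 0.0525.

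Alternatives for the RNA values were pseudocounts of 0.1 and 0.01, no filter, an FPKM of at least 5, median ratio scaling, TPM scaling, quantile normalization, eBayes without a trend, only the lines compared, the replicate number as a block, no minimum fold, and leaving out each library in turn. Those for domains were unmerged ends, domains of at least 100 kb, the upper part of the score, tolerances of 20 and 100 kb, overlaps of 50% and 90%, products of fold changes and genes of at least 5 FPKM. Alternatives chosen after seeing the data were leaving out genes with a failed status, scaling to the sum without small RNA and mitochondrial genes, shifts without stretches of over 2 Mb that hold no domain, locus midpoints, genes called after median ratio scaling, and the estimated correlation for arms.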

Results

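Chromatin domains and gene expression were measured in 3 human lung cell lines grown in culture. DMS153 and H209 are established lines of small cell lung carcinoma, a tumour type with features of neuroendocrine cells, and MRC5 is a noncancerous line of lung fibroblasts. Hi-C, which counts contacts between distant parts of the genome after crosslinking and ligation, was run on 1 library per line and is represented by a list of chromatin domains for each. RNA-seq was run on 3 libraries of DMS153, 2 of H209 and 3 of MRC5, and gives an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each listed gene. The labels number the RNA replicates but do not say whether they came from separate cultures, so p-values here measure only the spread between these libraries, which may be technical. The design asks how the carcinoma lines differ from the fibroblasts, and from each other, in gene expression and in domain structure.

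Between 13425 and 13560 genes reached an FPKM of 1 in the MRC5 libraries, 15963 and 16053 in the H209 libraries and 16462 to 16580 in the DMS153 libraries. The files hold no read counts, and the low values of the libraries put their depth at 0.953 to 1.66 times that of MRC5 replicate 1. The deposited confidence interval of a gene at an FPKM of 1 to 10 extended to either side by a median of 10.6% to 13.6% of the value, and that of a gene above 100 FPKM 3.35% to 3.61%. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.985 to 0.992 between DMS153 libraries, 0.994 between H209 libraries and 0.994 to 0.996 between MRC5 libraries. They were 0.771 to 0.789 between DMS153 and H209, 0.566 to 0.571 between DMS153 and MRC5 and 0.654 to 0.659 between H209 and MRC5. The DMS153 libraries stood apart in short RNA. Loci of microRNAs held 39.4% to 43.7% of their summed FPKM, against at most 0.0192% in any library of the other lines. Loci of Y RNA summed to a mean of 3004 FPKM in DMS153, 4.56 in H209 and 2.47 in MRC5, and those of 5S ribosomal RNA to 22.6, 0.312 and 1.85. Mitochondrial genes held 4.42% to 6.08% of the sum in DMS153, at least 12.8% in H209 and 11.2% to 12.5% in MRC5. The sum in DMS153 includes the microRNA loci, and MT-CO1, MT-CO3, MT-ATP6 and MT-ATP8 were listed at 0 with a failed status in all DMS153 libraries, as was MT-CO1 in all MRC5 libraries, so these shares do not measure mitochondrial RNA alone.

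Most of the neuroendocrine, epithelial and cell division genes tested were higher in DMS153 than in the fibroblasts, and most of the matrix and contractile genes were lower. INSM1 (ENSG00000173404.3, chromosome 20, 20348765 to 20351590 in hg19), a neuroendocrine transcription factor, stood at 196 ± 36.3 FPKM (SD, n = 3) and NKX2-1, a transcription factor of lung epithelium, at 69.0 ± 1.25 FPKM, and both were listed at 0 in all 3 MRC5 libraries. VIM (ENSG00000026025.9, chromosome 10, 17270258 to 17279592), which encodes the intermediate filament vimentin, stood at 0.101 ± 0.0222 FPKM against 1764 ± 139 in MRC5. Of 19066 genes tested, 6489 were higher and 3123 lower in DMS153 (limma, Benjamini-Hochberg adjusted p below 0.05 and a log2 fold change of at least 1). The genes tested include loci of microRNA and Y RNA, of which 248 and 108 averaged at least 1 FPKM in DMS153. In MRC5 11 and 1 did so. The median gene was 0.44 log2 units higher in DMS153, so the median of a gene list against MRC5 is given as a relative median, the list's median minus that of all genes. Fold changes of single genes, on the scale of log2(FPKM + 1), include that shift.

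Among neuroendocrine markers, 33 of 35 tested members were higher in DMS153 and 1 lower, with a relative median of 5.41 (camera, adjusted p = 1.82e-08, and adjusted p = 0.0762 with an estimated correlation). For this list and every other in the text, the counts of called members were identical when p-values were adjusted over the list alone. CHGA, which encodes the granule protein chromogranin A, was 8.07 ± 0.14 log2 units higher (SE, limma adjusted p = 6.86e-11). GRP, the precursor of gastrin-releasing peptide, stood at 776 ± 19.2 FPKM and CALCA, the calcitonin precursor, at 391 ± 121 FPKM. DLL3, an inhibitory Notch ligand, stood at 99.02 ± 5.11 FPKM against 0.202 ± 0.0260 in MRC5. UCHL1, a ubiquitin hydrolase of neurons that is also on this list, was the 1 lower member, at 269 FPKM against 734. Of 39 neuronal and synaptic genes, 34 were higher and none lower, among them KIF1A, an axonal motor protein, at 220 ± 8.31 FPKM against 0.118 (adjusted p = 2.77e-07, and 0.0244 with an estimated correlation).

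Of 29 epithelial markers, 28 were higher, led by EPCAM at 290 ± 35.2 FPKM and CDH1 (E-cadherin) at 202 ± 14.0 FPKM, and CLDN1 was lower (adjusted p = 4.88e-07, and 0.237 with an estimated correlation). Of 48 fibroblast and extracellular matrix genes, 46 were lower and none higher, with a relative median of -6.72 (adjusted p = 7.40e-23, and 0.0117 with an estimated correlation). DCN, which encodes the proteoglycan decorin, stood at 0.0434 FPKM against 2401 ± 74.9, and COL1A1, a chain of type I collagen, was listed at 1.02 ± 0.250 FPKM against 1171 ± 72.9. Of 34 contractile and focal adhesion genes, 30 were lower and none higher, for example MYL9, a myosin light chain, at 0.144 FPKM against 311 (adjusted p = 7.78e-15, and 0.0762 with an estimated correlation). Of 25 genes that mark non-neuroendocrine small cell lung cancer, 23 were lower and 2 higher (adjusted p = 7.56e-11, and 0.0117 with an estimated correlation). They included YAP1, a coactivator of the Hippo pathway, at 0.416 ± 0.0249 FPKM against 55.4 ± 5.37, and REST, a repressor of neuronal genes, at 0.0486 FPKM against 8.02 ± 1.05. HES1 and EMP2 were the 2 higher members. Of 30 inflammatory and secretory genes, 22 were lower and 1 higher (adjusted p = 1.31e-10, and 0.0274 with an estimated correlation).

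All but 1 of 37 mitosis and cell cycle genes were higher in DMS153, with a relative median of 3.45 (adjusted p = 2.91e-08, and 0.237 with an estimated correlation). MKI67, a marker of cycling cells, stood at 101 ± 11.4 FPKM against 0.962 ± 0.117. Of 36 DNA replication genes, 33 were higher, such as GINS2 at 38.2 ± 1.56 FPKM against 0.768 (adjusted p = 4.88e-07, and 0.270 with an estimated correlation). Of 30 DNA damage repair genes, 26 were higher (adjusted p = 3.56e-05, and 0.197 with an estimated correlation). Among 28 cyclin-dependent kinase inhibitors and DNA damage response targets, 16 were lower and 6 higher (adjusted p = 0.000193, and 0.0762 with an estimated correlation). CDKN1A, which encodes the inhibitor p21, stood at 24.9 ± 4.09 FPKM against 772 ± 40.1, whereas CDKN2A, the gene of p16, was higher at 144 ± 3.74 FPKM against 18.7 ± 3.33. Of 33 chromatin architecture proteins, 22 were higher and 1 lower (adjusted p = 0.00117, and 0.332 with an estimated correlation), the lower being LMNA, which encodes lamins A and C. The cohesin subunit gene STAG2 stood at 149 ± 9.18 FPKM against 15.8 ± 0.368, and CTCF, which encodes the insulator protein of domain boundaries, at 28.0 ± 2.48 FPKM against 10.1 ± 0.0589. Of 37 Polycomb and chromatin modifiers, 26 were higher and none lower, with EZH2, a histone H3 lysine methyltransferase, at 55.8 ± 3.48 FPKM against 2.06 ± 0.224 (adjusted p = 5.20e-05, and 0.197 with an estimated correlation). All 9 tested HOXD genes were higher, HOXD10 at 83.4 ± 4.95 FPKM against 0.000817 (adjusted p = 0.000470, and 0.279 with an estimated correlation).

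Ribosomal, glycolysis, stress and antigen presentation genes were lower in DMS153 relative to all genes. Of 36 ribosomal protein genes, 17 were lower and none higher, with a relative median of -1.36 (adjusted p = 3.49e-09, and 0.344 with an estimated correlation). Of 22 glycolysis genes, 14 were lower and 1 higher (adjusted p = 1.37e-05, and 0.197 with an estimated correlation). Of 25 unfolded protein and amino acid stress genes, 15 were lower, CHAC1 at 3.21 FPKM against 87.1 (adjusted p = 1.80e-06, and 0.247 with an estimated correlation). Of 18 genes of MHC class I antigen presentation, 8 were lower and none higher, HLA-E at 2.04 ± 0.871 FPKM against 166 ± 8.67 (adjusted p = 6.66e-05, and 0.259 with an estimated correlation). Of 24 cholesterol synthesis genes, 18 were higher (adjusted p = 0.000401, and 0.319 with an estimated correlation). In all, 27 of 39 tested lists passed the threshold, and 4 did so with an estimated correlation: fibroblast and matrix, non-neuroendocrine, neuronal and synaptic, and inflammatory genes.

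MYC, the oncogene, was lower in DMS153, at 2.85 ± 0.584 FPKM against 31.1 ± 2.07 in MRC5, and its paralog MYCL was higher, at 56.0 ± 7.84 FPKM against 0.0663. RB1, a tumour suppressor of the cell cycle, stood at 4.49 ± 0.348 FPKM against 12.4 ± 1.43, a log2 fold change of -1.28 ± 0.09 (SE, limma adjusted p = 9.74e-07). The antiapoptotic gene BCL2 stood at 45.7 ± 5.44 FPKM against 0.618 ± 0.248. POU2F3 and MYCN, which mark other small cell lung cancer classes, stayed under 1 FPKM in every library. The 2 sides of this comparison depend on scaling. After median ratio scaling 4637 genes were higher and 4890 lower (median gene at -0.0494), with quantile normalization 4242 and 4432 (-0.0308), and with TPM scaling 5750 and 4527 (0.13). Scaling without small RNA and mitochondrial genes gave 7737 and 2513 (0.68). CTCF fell below the minimum fold, with log2 fold changes of 0.78 and 0.99 under median ratio and TPM scaling.

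In H209, most of the neuroendocrine, epithelial and cell division genes tested were also higher than in MRC5, and most of the matrix and contractile genes lower. INSM1 stood at 294 ± 0.498 FPKM (SD, n = 2) and NKX2-1 at 87.4 ± 1.61 FPKM, both listed at 0 in the 3 MRC5 libraries. NEUROD1 (ENSG00000162992.3, chromosome 2, 182537815 to 182545603), another neuroendocrine transcription factor, reached 72.0 ± 11.1 FPKM and was also listed at 0 in MRC5. CHGA stood at 356 ± 7.96 FPKM, SCNN1A, an epithelial sodium channel subunit, at 380 ± 26.9 FPKM, and VIM at 0.765 ± 0.181 FPKM. Against MRC5, 6300 genes were higher and 2839 lower in H209, and the median gene was 0.46 log2 units higher.

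Of 35 neuroendocrine markers, 32 were higher and none lower in H209, with a relative median of 4.82 (camera, adjusted p = 3.72e-08, and 0.0767 with an estimated correlation). Of 39 neuronal and synaptic genes, 34 were higher and 2 lower, with ELAVL3, a neuronal RNA-binding protein, at 101 ± 3.37 FPKM against 0.0166 (adjusted p = 4.09e-07, and 0.0231 with an estimated correlation). NLGN1 and RAB3B were the 2 lower members. Of 29 epithelial markers, 26 were higher and 1 lower, with SPINT2, a protease inhibitor, at 292 ± 4.90 FPKM against 0.435 (adjusted p = 3.70e-07, and 0.233 with an estimated correlation). Of the fibroblast and matrix genes, 46 of 48 were lower, such as COL6A3 at 0.0734 FPKM against 912 ± 63.7 (adjusted p = 1.00e-26, and 0.00894 with an estimated correlation). Of the non-neuroendocrine markers, 22 of 25 were lower and 2 higher, the lower ones led by CTGF, a target of YAP signalling, at 0.0534 FPKM against 685 ± 16.7 (adjusted p = 3.99e-12, and 0.00894 with an estimated correlation). Of the contractile and focal adhesion genes, 30 of 34 were lower (adjusted p = 6.19e-17, and 0.0686 with an estimated correlation), and of the inflammatory and secretory genes 21 of 30 were lower and 1 higher (adjusted p = 1.94e-11, and 0.0231 with an estimated correlation).

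All 37 mitosis and cell cycle genes were higher in H209, UBE2C at 142 ± 4.75 FPKM against 3.62 ± 0.487 (adjusted p = 1.29e-08, and 0.233 with an estimated correlation). Of 36 DNA replication genes, 35 were higher, MCM2 at 105 ± 2.36 FPKM against 3.51 ± 0.328 (adjusted p = 4.64e-08, and 0.238 with an estimated correlation). Of 18 genes of MHC class I antigen presentation, 14 were lower and none higher, with a relative median of -3.23 (adjusted p = 2.77e-09, and 0.149 with an estimated correlation). HLA-B stood at 1.42 ± 0.255 FPKM against 342 ± 27.3 and HLA-C at 1.77 ± 0.470 FPKM against 382 ± 50.1, with the limit that reads of these similar genes can be assigned to one another. Of 32 interferon response genes, 21 were lower and 5 higher, IFITM3 at 2.04 ± 0.350 FPKM against 583 ± 61.3 (adjusted p = 9.60e-08, and 0.149 with an estimated correlation). Of 13 cancer testis antigens, 10 were higher, PRAME at 145 ± 2.87 FPKM (adjusted p = 0.00130, and 0.0767 with an estimated correlation). Of 9 HOXD genes, 8 were higher (adjusted p = 0.00113, and 0.291 with an estimated correlation).

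MYC was at 0.108 ± 0.0471 FPKM in H209 and MYCL at 152 ± 3.77 FPKM, a log2 fold change of 7.17 ± 0.11 against MRC5 (SE, limma adjusted p = 5.78e-11). RB1 stood at 23.5 ± 1.13 FPKM against 12.4 ± 1.43, a log2 fold change of 0.88 that missed the minimum and reached 1.11 with TPM scaling. In all, 24 of 39 lists passed the threshold, the same 4 lists as in DMS153 with an estimated correlation. Median ratio scaling gave 3877 genes higher and 4772 lower (median gene at -0.0302) and quantile normalization 4086 and 3800 (0.0325). TPM scaling gave 8444 and 2787 (0.70), and scaling without small RNA and mitochondrial genes 7365 and 2459 (0.64). The list of HOXA genes was called higher (adjusted p = 0.0491, and 0.285 with an estimated correlation), a call that ended under 7 other settings and when any of 5 single libraries was left out (DMS153 replicates 1, 2 and 3, H209 replicate 2 and MRC5 replicate 1), with adjusted p from 0.0508 to 0.123.

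**Figure D1:**
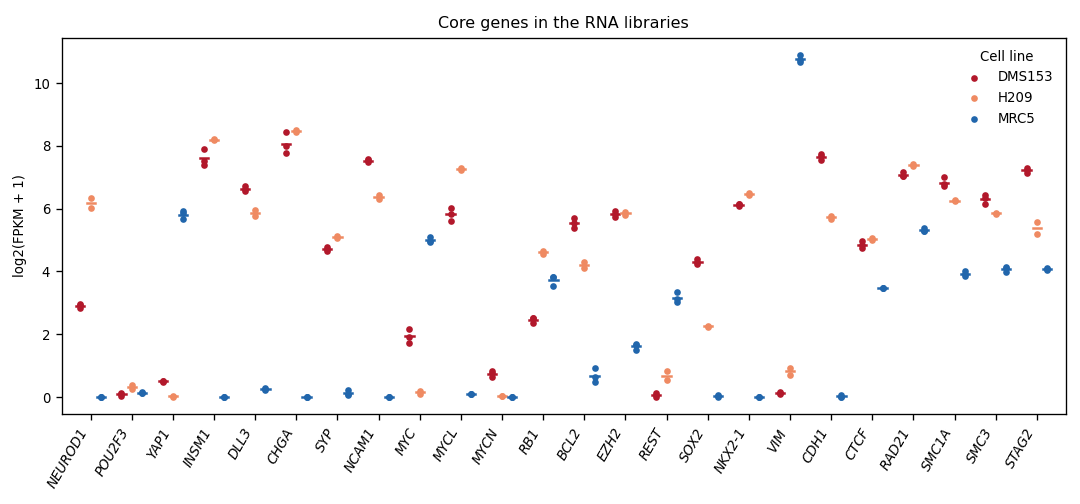
Expression of 24 of the 27 core genes as log2(FPKM + 1) on the vertical axis, with 1 point per RNA library (3 of DMS153, 2 of H209, 3 of MRC5) and a bar at each mean. INSM1 sits near 196 FPKM in DMS153, near 294 FPKM in H209 and at 0 in MRC5, and VIM near 1764 FPKM in MRC5 alone.

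The carcinoma lines shared much of what set them apart from the fibroblasts. Genes higher in both lines numbered 4055, where independent lists of these lengths would share 2144, and genes lower in both numbered 2165, where independent lists would share 465. In 20 simulations of unchanged lines, all 8 libraries were drawn around 1 mean per gene, and the lines were compared with the same 3 simulated MRC5 libraries. No call was shared, but such data give almost no calls at all, so that absence decides nothing about shared controls. Across genes, log2 fold changes of the lines against MRC5 correlated at r = 0.756, against a mean of 0.452 for simulated unchanged lines, and their covariance was 2.56 against a simulated 0.00771. The highest simulated covariance was 0.0105, which argues against independent noise of the shared MRC5 libraries as the source of the excess. The 3 MRC5 libraries could not be divided into 2 groups of 2. Whatever sets MRC5 itself apart enters both comparisons, so part of the excess may still come from the shared controls. A further 58 genes, some of them microRNA loci, were higher in DMS153 and lower in H209, and 62 were lower in DMS153 and higher in H209. All 120 also passed the direct test between the carcinoma lines, which adds no separate support. The comparisons come from 1 fit, so opposite calls against MRC5 already imply a difference between the lines beyond the minimum fold. After median ratio scaling the shared genes numbered 2600 higher and 3680 lower.

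The carcinoma lines differed from each other in single genes such as NEUROD1, SOX2, MYC, MYCL and RB1, and at the preset correlation in the lists of antigen presentation and HOXA, HOXC and HOXD genes. With an estimated correlation none of these lists passed, and HOXA, HOXC and HOXD each lost their call under at least 1 other setting. In the direct comparison, 2622 genes were higher and 2547 lower in DMS153 than in H209, and the median gene differed by -0.0411 log2 units. The genes tested include the microRNA and Y RNA loci that set the DMS153 libraries apart. Of these, 248 and 108 averaged at least 1 FPKM in DMS153, against 8 and 1 in H209. Counts without these loci are not given. NEUROD1 stood at 6.55 ± 0.413 FPKM in DMS153 (SD, n = 3) against 72.0 ± 11.1 in H209 (n = 2), a log2 fold change of -3.27 ± 0.10 (SE, limma adjusted p = 1.64e-08). MYCL was lower in DMS153, with a log2 fold change of -1.44, and MYC higher, with 1.79. RB1 was lower, at 4.49 FPKM against 23.5, a log2 fold change of -2.16. SOX2, a transcription factor of stem cells and lung epithelium, stood at 18.9 ± 1.03 FPKM against 3.76 ± 0.0860, CDH1 at 202 ± 14.0 FPKM against 51.8 ± 2.73, and STAG2 at 149 ± 9.18 FPKM against 41.2 ± 7.95.

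Of 35 neuroendocrine markers, 17 were higher in DMS153 and 5 lower, with a median of 0.88 (camera, adjusted p = 0.0239, and 0.573 with an estimated correlation). The receptor tyrosine kinase gene RET stood at 14.0 ± 1.24 FPKM against 0.0454 and CALCA at 391 ± 121 FPKM against 38.1 ± 1.57, while ISL1, a transcription factor, was lower at 6.21 ± 1.27 FPKM against 57.1 ± 1.98. TPH1, which makes the first step of serotonin synthesis, stood at 335 ± 98.6 FPKM against 1.86 ± 0.298, and FABP5, a fatty acid binding protein, at 264 ± 13.4 FPKM against 0.171. Of 18 genes of MHC class I antigen presentation, 10 were higher in DMS153 and none lower, with a median of 1.19 (adjusted p = 0.000267, and 0.564 with an estimated correlation). HLA-C stood at 200 ± 34.9 FPKM against 1.77 ± 0.470 and HLA-B at 52.6 ± 9.99 FPKM against 1.42 ± 0.255. Of 32 interferon response genes, 11 were higher and 1 lower, with IFI16, a DNA sensor, at 12.1 ± 1.48 FPKM against 0.129 (adjusted p = 0.0184, and 0.630 with an estimated correlation). The list's median of 0.30 was 0.19 without DMS153 replicate 3, and -0.0068 with TPM scaling, where the median gene was at -0.59.

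Of 15 replication-dependent histone genes, 12 were lower in DMS153, with a median of -1.55 and HIST1H1C, a linker histone, at 3.72 ± 0.409 FPKM against 31.0 ± 2.61 (adjusted p = 0.000912, and 0.564 with an estimated correlation). The HOX clusters differed in direction. Of 9 HOXD genes, 5 were higher in DMS153 (median 1.23, adjusted p = 0.00452, and 0.613 with an estimated correlation), whereas 4 of 5 HOXC genes (median -1.70, adjusted p = 0.0163, and 0.415 with an estimated correlation) and 4 of 8 HOXA genes (median -0.87, adjusted p = 0.0239, and 0.564 with an estimated correlation) were lower. HOXA7 stood at 0.493 FPKM against 21.8 ± 2.65 and HOXC9 at 0.0669 FPKM against 7.64 ± 0.460. Of 39 clustered protocadherins, 15 were lower and 3 higher (median -0.70, adjusted p = 0.00452, and 0.573 with an estimated correlation). Their median was -0.22 without H209 replicate 1 and -0.23 without H209 replicate 2. With 1 H209 library left, genes that reach 1 FPKM in H209 alone are no longer tested, so the members differ. Of 13 cancer testis antigens, 8 were lower and 3 higher (median -1.17, adjusted p = 0.0308, and 0.415 with an estimated correlation), with MAGEA4 at 0.00227 FPKM against 18.2 ± 3.48 and GAGE2A at 12.5 ± 0.509 FPKM against 0.00286. The median of cancer testis antigens was -0.78 without H209 replicate 1 and -0.69 without H209 replicate 2, where the test pointed in the other direction. Their call ended in both cases, but the same loss of genes expressed in H209 alone applies, so this does not measure dependence on a single library. Members of the MAGE, GAGE and protocadherin families have near-identical copies or shared exons, so the split of reads among them is uncertain. Of 11 ciliated cell markers, 6 were higher, FOXJ1, the transcription factor of motile cilia, at 19.8 ± 3.91 FPKM against 2.87 ± 0.188 (median 1.41, adjusted p = 0.00452, and 0.415 with an estimated correlation).

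Of 22 glycolysis genes, 8 were lower and 2 higher (median -0.81, adjusted p = 0.0307, and 0.630 with an estimated correlation), and of 33 nuclear oxidative phosphorylation genes 4 were lower and none higher (median -0.51, adjusted p = 0.00833, and 0.731 with an estimated correlation). All 4 tested skeletal and cardiac muscle markers were higher, TNNT1 at 113 ± 4.83 FPKM against 11.3 ± 1.40 (median 1.57, adjusted p = 0.0274, and 0.415 with an estimated correlation). The host transcripts MIR17HG (2157 ± 139 FPKM against 1.74) and MIR22HG (1197 ± 114 FPKM against 1.03) led the higher genes apart from small RNA, unnamed clones and mitochondrial genes, and both are hosts of microRNAs, the class of loci that sets the DMS153 libraries apart. TPM scaling, which the microRNA sum of DMS153 enters, moved the median gene to -0.59 and gave 1814 genes higher and 6630 lower. It ended the calls of NCAM1 (0.52) and BCL2 (0.71), whose fold changes include that shift of all genes. None of the 13 called lists kept its call with an estimated correlation, and 8 lost it under at least 1 other setting.

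**Figure D2:**
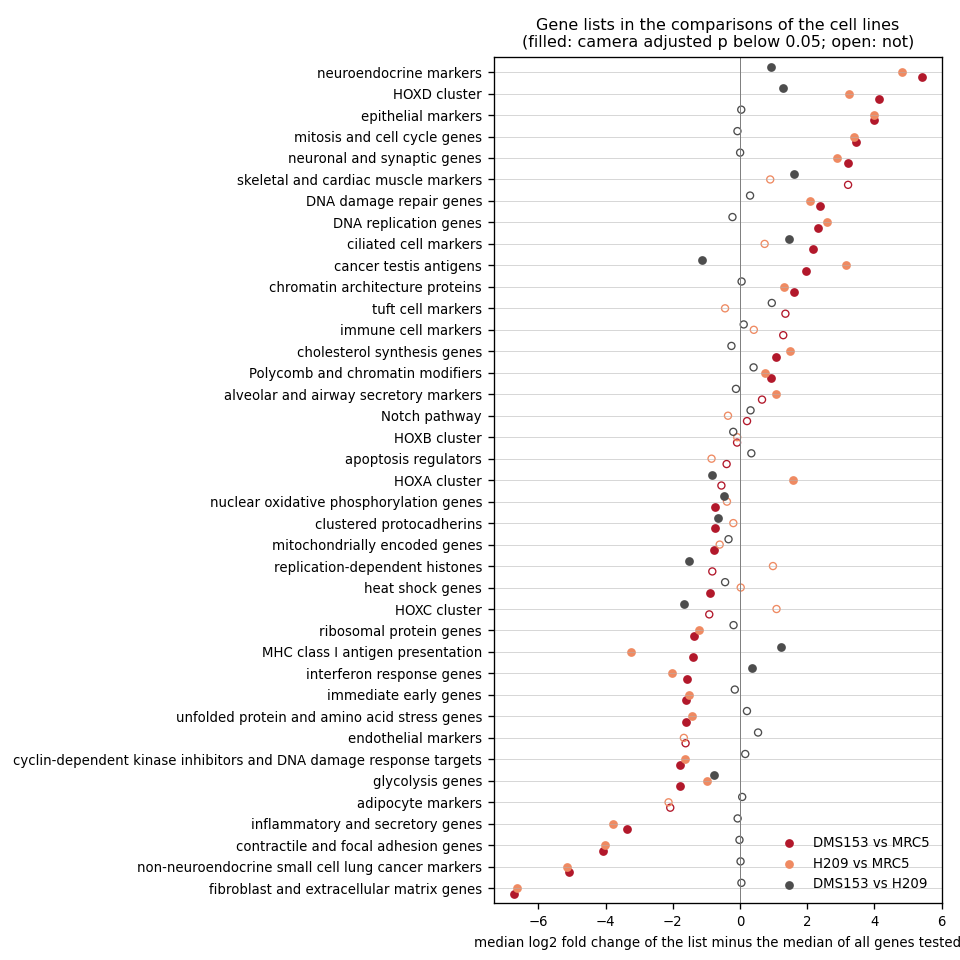
Median log2 fold change of each of 39 gene lists minus the median of all genes tested (horizontal axis), in DMS153 against MRC5, H209 against MRC5 and DMS153 against H209, with filled points where camera with the preset correlation passed an adjusted p of 0.05. Fibroblast and matrix genes lie at -6.72 in DMS153 and -6.65 in H209 against MRC5, and neuroendocrine markers at 5.41 and 4.82.

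Genes of whole chromosome arms shifted together. In both carcinoma lines, genes of 3p, 4p, 5q and 8p were lower than other genes relative to MRC5 and genes of 5p higher. On 3p, 154 of 464 tested genes were lower and 87 higher in DMS153, with a relative median of -0.83 (camera, adjusted p = 1.63e-05), and 138 were lower and 66 higher in H209, with a relative median of -0.78 (adjusted p = 6.99e-07). In DMS153 and H209 the relative medians were -0.78 and -0.59 on 5q, -0.80 and -0.58 on 8p, -0.70 and -0.46 on 4p, and 0.55 and 0.65 on 5p. On 4p in H209, 45 genes were higher and 43 lower than in MRC5, with a median log2 fold change of 0. Those genes were thus lower only relative to other genes. DMS153 alone passed the threshold for lower genes on 10p, 15q, 17p and 18p and for higher genes on 1q, 7p and 21q. Between the carcinoma lines, 148 of 324 genes of 17p were lower in DMS153 and 10 higher (relative median -0.89, adjusted p = 4.34e-13), and 56 of 87 genes of 18p were lower and 3 higher (relative median -1.27, adjusted p = 2.17e-10). Genes of 15q, 10p, 6p, 19p and 19q were also lower in DMS153 than in H209, and genes of 1p, 1q, 4q, 6q, 7p, 7q, 21q and Xq higher. With an estimated correlation, 5 of the 12 arms called in DMS153 against MRC5 kept their call (3p, 4p, 5q, 10p and 15q, each at adjusted p = 0.0397), and none of the 5 in H209 (3p at 0.104, 5q at 0.128, 4p at 0.225, 5p at 0.332 and 8p at 0.496). In DMS153 the adjusted p with an estimated correlation was 0.279 for 8p, 0.300 for 17p and 0.200 for 5p. Between the lines 5 of the 15 arms kept their call (1p, 1q, 10p, 15q and 18p), and 17p was at 0.115. The call of 5p in H209 ended without H209 replicate 1 (adjusted p = 0.0777) and without H209 replicate 2 (0.0547), and 4q between the lines ended without H209 replicate 2 (0.0535). The call of 21q in DMS153 ended without H209 replicate 1 (0.0580), H209 replicate 2 (0.0590), MRC5 replicate 1 (0.0510) or MRC5 replicate 3 (0.0553). It also ended with a pseudocount of 0.01 (0.0553), no filter on low values (0.280), an FPKM of at least 5 (0.166), median ratio scaling (0.0969), TPM scaling (0.0691), the replicate number as a block (0.0512) and only the lines compared (0.0603). Without a filter, calls ended in DMS153 and H209 for 5p (0.362 and 0.675), 4p (0.0977 and 0.638) and 8p (0.0973 and 0.0698), and in DMS153 for 1q (0.171) and 7p (0.100). Scaling without small RNA and mitochondrial genes ended the calls of 5p (0.0504 and 0.0794). In H209 TPM scaling ended that of 5p (0.0731) and median ratio scaling that of 4p (0.0637). Between the lines the calls of 4q, 6q, 7q, 21q and Xq ended without a filter (0.0811 to 0.353), those of 4q, 6q and 21q with TPM scaling (0.0622 to 0.110), and that of 21q with pseudocounts of 0.1 (0.0502) and 0.01 (0.0562).

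**Figure D3:**
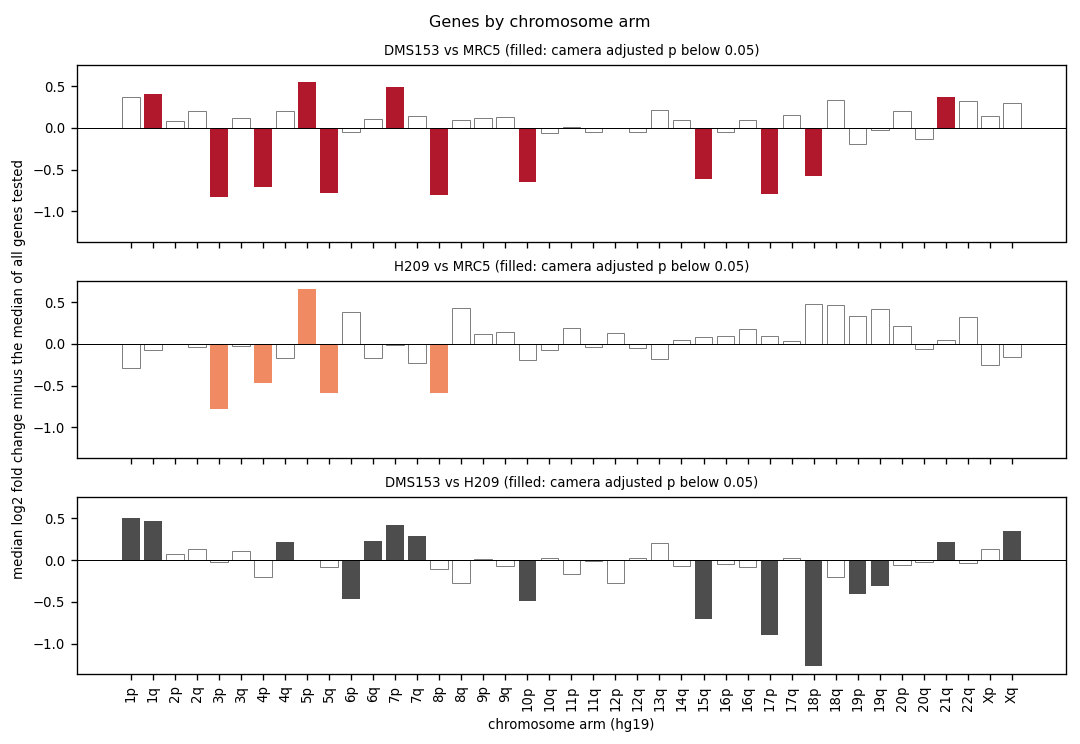
Median log2 fold change of the genes of each of 41 chromosome arms minus the median of all genes tested (vertical axis), in a panel per comparison, with filled bars where camera with the preset correlation passed an adjusted p of 0.05. The bar of 3p reaches -0.83 in DMS153 and -0.78 in H209, and that of 18p -1.27 between the carcinoma lines.

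The Hi-C files list 5023 domains in DMS153, 3987 in H209 and 3701 in MRC5, on a 20 kb grid of hg19. With 1 library per line there are no replicates, so these values describe the libraries and were not tested between lines. Domains were shorter in DMS153, with a median of 240 kb (quartiles 140 and 420 kb), than in H209 (300 kb, quartiles 160 and 560 kb) and MRC5 (300 kb, quartiles 180 and 540 kb). They covered 56.4% of the genome in DMS153, 58.4% in H209 and 54.4% in MRC5. After merging ends within 20 kb, DMS153 had 7801 boundaries, H209 6321 and MRC5 5914. The number of sequenced contacts is not in the files, and it bears on how many domains are found.

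Most boundaries of one line lay near a boundary of another. Of DMS153 boundaries, 61.2% lay within 40 kb of an MRC5 boundary (95% exact binomial interval 60.1% to 62.3%). The mean over 1000 circular shifts of the MRC5 boundaries along each chromosome was 15.6%. For H209 boundaries near MRC5 ones the share was 70.1% (68.9% to 71.2%) against 15.7%, and for DMS153 boundaries near H209 ones 70.0% (69.0% to 71.0%) against 16.6%. In the other direction, 79.7% of MRC5 boundaries lay near DMS153 ones and 74.4% near H209 ones, and 85.4% of H209 boundaries lay near DMS153 ones. Every one of these shares exceeded all 1000 shifts. The intervals cover counting error only. In DMS153, 4067 boundaries lay near boundaries of both other lines and 1635 (20.96%) near those of neither, compared with 541 (8.56%) in H209 and 823 (13.9%) in MRC5. Domains of DMS153 had a domain of at least 80% reciprocal overlap in MRC5 in 43.3% of cases and in H209 in 55.2%, and domains of H209 had one in MRC5 in 53.3%.

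**Figure D4:**
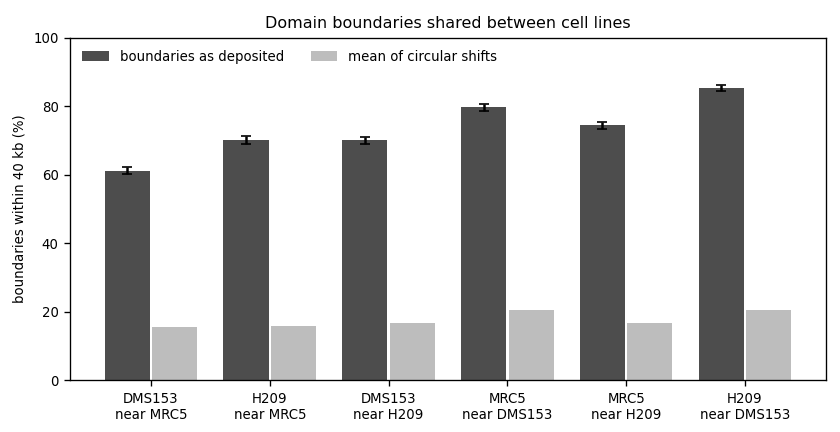
Share of the boundaries of one line that lie within 40 kb of a boundary of another line (vertical axis in percent, dark bars with 95% exact binomial intervals) beside the mean share over 1000 circular shifts (light bars). The dark bars range from 61.2% to 85.4% and the light ones from 15.6% to 20.5%.

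Domains around the core genes ranged from identical to different in extent. INSM1 lay in a domain of 220 kb with the same ends in all 3 lines (chromosome 20, 20340000 to 20559998), DLL3 in one of 120 kb (chromosome 19, 39920000 to 40039998) and SOX2 in one of 1000 kb (chromosome 3, 181420000 to 182419998), although these genes were far higher in the carcinoma lines. MYC lay in a domain of 2000 kb in H209 and MRC5 (chromosome 8, 128740000 to 130739998) and in one of 940 kb in DMS153, which started at the same place and ended at 129679998. In each line 2000 kb was also the largest size listed, so the end in H209 and MRC5 may reflect a limit on domain size. The domain holding NKX2-1 measured 1360 kb in MRC5, 800 kb in H209 and 540 kb in DMS153. The domain holding MYCL measured 260 kb in MRC5 and 100 kb in both carcinoma lines, and that of CDH1 100 kb in MRC5 and 320 kb in both carcinoma lines. RB1 lay in a domain of 260 kb in MRC5, 500 kb in H209 and 480 kb in DMS153. For NEUROD1 a domain was listed in H209 alone (180 kb), and for CHGA, NCAM1 and YAP1 in DMS153 alone (80, 700 and 260 kb).

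**Figure D5:**
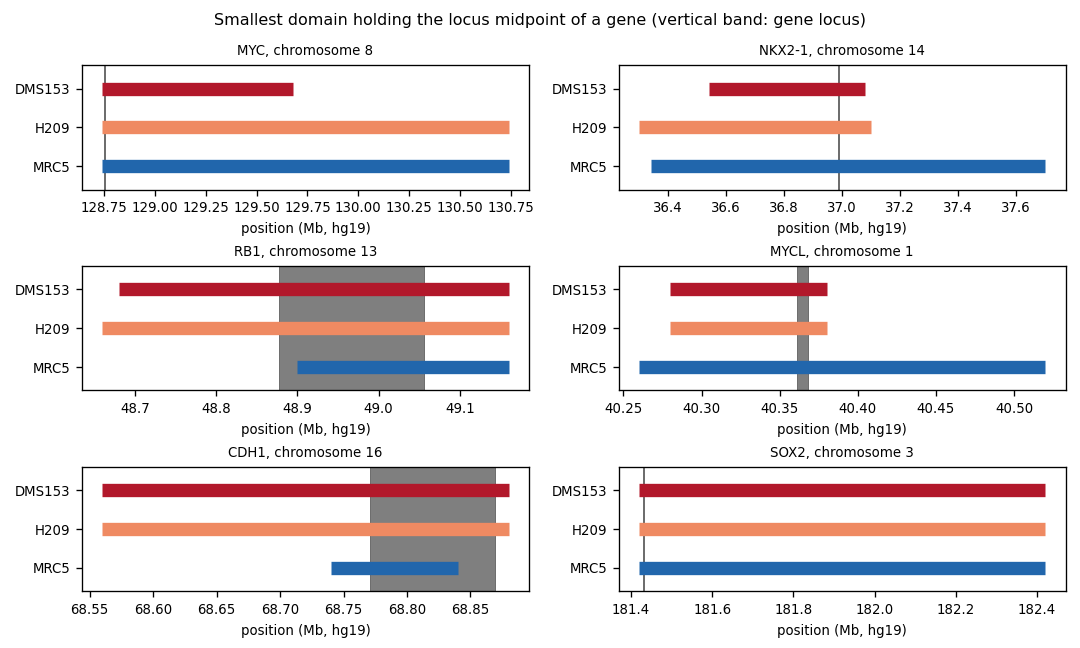
Smallest listed domain that holds the locus midpoint of MYC, NKX2-1, RB1, MYCL, CDH1 and SOX2 in each line, drawn as a bar along the chromosome (horizontal axis, Mb in hg19), with the gene locus as a vertical band. The MYC domain spans 940 kb in DMS153 and 2000 kb, the largest size listed, in the other lines, and the SOX2 domain 1000 kb in all 3.

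Genes higher in DMS153 than in MRC5 lay more often near boundaries that MRC5 lacked. Of 6481 such genes, 18.99% had a locus within 40 kb of 1 of the 3029 boundaries gained in DMS153, against 15.0% of the other tested genes, a log2 odds ratio of 0.41, where shifted boundaries gave a mean of 0.11 (permutation by circular shift, p = 0.001, the smallest that 1000 shifts can give, and 0.00899 adjusted over 18 such tests). They lay less often near boundaries shared with MRC5, 35.0% against 38.2% (log2 odds ratio -0.20, adjusted p = 0.00899), and genes lower in DMS153 more often, 42.1% against 36.1% (0.37, adjusted p = 0.00899). In H209, higher genes also lay less often near shared boundaries, 33.2% against 35.83% (-0.17, adjusted p = 0.00899). The other 14 tests, among them all 6 of boundaries lost in a carcinoma line, did not pass. They include higher genes near gained boundaries in H209, 12.8% against 11.4% (log2 odds ratio 0.19, adjusted p = 0.170). The first result that passed did not hold when the locus midpoint stood for the gene (log2 odds ratio 0.21 against a shifted mean of -0.00845, adjusted p = 0.108). The third did not hold within 20 kb (0.27, adjusted p = 0.141). Loci of microRNA and Y RNA are among the genes higher in DMS153, and results without them are not given.

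Adjacent genes changed more alike when no boundary lay between them. Over 12654 pairs matched on gap length, the absolute difference in log2 fold change between DMS153 and MRC5 was smaller for pairs with no DMS153 boundary in their gap than for pairs with one, by a mean difference of -0.32, where shifted boundaries gave -0.0205. With MRC5 boundaries the difference was -0.36. For H209 against MRC5 it was -0.24 with H209 boundaries and -0.30 with MRC5 boundaries. All 4 differences lay beyond all 1000 shifts (permutation by circular shift, p = 0.001). None passed when the mean product of the fold changes replaced the absolute difference (adjusted p = 0.809 for DMS153 boundaries and 0.553 for the others). The longest run of adjacent genes called in the same direction inside a domain of DMS153 was 10 higher genes from HOXD9 to HOXD1 (chromosome 2, domain 176980000 to 177519998). Their median log2 fold change was 4.25, and MRC5 had a domain of at least 80% reciprocal overlap there. The run includes the locus of MIR10B, at 1089 FPKM in DMS153 and 0 in MRC5, which belongs to the microRNA signal of the DMS153 libraries. In H209 a run as long as any there held 9 higher genes starting with KCTD19 (chromosome 16, 67280000 to 67519998).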

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

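The tests of liver and blood cell markers and of other splits of the samples, the estimated correlation for arms, the scaling without small RNA and mitochondrial genes and the locus midpoint were chosen after the results they bear on were seen, and the other tests reported here before. The results in this part are differences between the carcinoma lines in how far they depart from MRC5, which equal the direct comparison of DMS153 with H209, and a signal in the summed microRNA loci, which no gene list covers, although single loci are among the tested and called genes. The differences in genes were tested with limma and those in lists with camera at the preset correlation.

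Several core genes differed between the carcinoma lines, each with no overlap between the libraries of the lines. The log2 fold changes of DMS153 against H209 were -3.27 for NEUROD1, -1.44 for MYCL and -2.16 for RB1, and 1.17 for NCAM1, a neural adhesion molecule, 1.79 for MYC, 1.33 for BCL2, 2.07 for SOX2, 1.94 for CDH1 and 1.84 for STAG2. With TPM scaling, which moved the median gene to -0.59, the calls of NCAM1 (0.52) and BCL2 (0.71) ended. Both lines lay on the same side of MRC5 for most of these genes. RB1 was the exception, lower than MRC5 in DMS153 and above it in H209 with a fold change of 0.88 that missed the minimum.

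Among lists, 13 differed between the lines. DMS153 had the higher median in neuroendocrine markers (0.88), MHC class I antigen presentation (1.19), interferon response genes (0.30), the HOXD cluster (1.23), ciliated cell markers (1.41) and skeletal and cardiac muscle markers (1.57). It had the lower median in replication-dependent histones (-1.55), glycolysis genes (-0.81), nuclear oxidative phosphorylation genes (-0.51), the HOXA cluster (-0.87), the HOXC cluster (-1.70), clustered protocadherins (-0.70) and cancer testis antigens (-1.17). With an estimated correlation none of these passed, and 8 lost their call under at least 1 other setting. Without DMS153 replicate 3 the interferon median was 0.19. TPM scaling moved the median gene to -0.59, the interferon median to -0.0068 and that of neuroendocrine markers to 0.24, and the other medians kept their sign. The median of protocadherins was -0.22 without H209 replicate 1 and -0.23 without H209 replicate 2. That of cancer testis antigens was -0.78 without H209 replicate 1 and -0.69 without H209 replicate 2, where the test pointed in the other direction. Both removals take genes expressed in H209 alone out of the test, so these values do not measure dependence on a single library. A further 120 genes were called in opposite directions against MRC5. Their calls between the lines largely follow from those opposite calls and add no separate support. CREBBP, a histone acetyltransferase, was 1.33 log2 units higher in DMS153 than in MRC5 and had a log2 fold change of -1.85 in H209, the first of these falling to 0.73 with median ratio scaling and 0.93 with TPM scaling, where the median gene moved from 0.44 to -0.0494 and 0.13, and HDAC9, a histone deacetylase, had 1.90 and -2.24.

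The summed FPKM of the 1376 microRNA loci averaged 344689 in DMS153, against 89.6 in H209 and 66.0 in MRC5. Of 31 loci with at least 1000 FPKM in DMS153, 30 were listed at 0 in all H209 and MRC5 libraries. The highest were MIR144 (99904 FPKM), MIR122 (68976), MIR486 (24863) and MIR148A (22614). MIR122 is a liver microRNA and MIR144 and MIR486 are red cell microRNAs, so 15 hepatocyte and 8 red cell and platelet genes were examined. Their median levels in DMS153 were 0.0369 and 0.0600 FPKM, the highest of them RBP4 at 8.53 FPKM, which H209 also expressed at 4.17 FPKM, and HBA2 at 0.205 FPKM. These levels argue against whole liver or blood cells as the source. The short length of the loci is argued against by snoRNAs, whose summed FPKM in DMS153 was 0.971 times that in H209, although other short transcripts did differ, with ratios of 659 for Y RNA, 72.6 for 5S ribosomal RNA and 1.42 for U RNA. Of the 31 loci, 19 had a tested host gene, which gave 18 distinct hosts. Their median log2 fold change against H209 was 0.11 (bootstrap interval -0.15 to 0.40), and none was called higher. This argues against transcription of the host genes as the whole cause for these loci. MIR144, MIR122 and MIR148A had no tested host, and genes listed under microRNA symbols were not taken as hosts, so host transcription stays open for the other loci. Reads of a small-RNA library or of another library in those of DMS153, and small RNA of the line itself, stay open and were not tested. MIR17HG and MIR22HG, the host transcripts among the most increased genes of DMS153 apart from small RNA, may carry the same signal.

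Genes of 3p were lower and genes of 5p higher than other genes in both carcinoma lines at the preset correlation. With an estimated correlation the call of 5p ended in DMS153 and H209 (adjusted p = 0.200 and 0.332) and that of 3p in H209 (0.104). The call of 5p also ended in both lines without a filter on low values (0.362 and 0.675) and with scaling without small RNA and mitochondrial genes (0.0504 and 0.0794). In H209 it ended with TPM scaling (0.0731), without H209 replicate 1 (0.0777) and without H209 replicate 2 (0.0547). The fixed lists hold 12 of the 464 tested genes of 3p and 5 of the 175 of 5p, too few for their absence to move a median, so the value without them (nearest to 0, 0.55) decides nothing. Within quartiles of locus length the median nearest to 0 was 0.23 and every quartile kept its side, which argues against locus length. A difference in DNA copy number would also move genes expressed in every library. Among genes of at least 5 FPKM in all 8 libraries the relative medians were -0.69 and -0.89 on 3p in DMS153 and H209 and 0.56 and 0.71 on 5p, so the median nearest to 0 was 0.56, which is consistent with copy number. No DNA measurement was analysed here, so copy number is a candidate explanation that stays untested as such, next to regulation of these regions by the state of the cells.

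Genes higher in DMS153 than in MRC5, loci of microRNA and Y RNA included, lay near boundaries that MRC5 lacks more often than other genes. With genes stratified by locus length the log2 odds ratio was 0.38, 4.38 SD above the mean of shifted boundaries. Stratified by the number of tested genes within 500 kb it was 0.39, 4.10 SD above, and without the arms called between DMS153 and MRC5 it was 0.43, 3.88 SD above. Length, density and shifted arms are therefore argued against as the whole cause. With the locus midpoint the log2 odds ratio was 0.21 against a shifted mean of -0.00845 and no longer passed (adjusted p = 0.108), where with the whole locus it was 0.41 against 0.11, and the difference between these settings was not tested. A depth of the Hi-C library of DMS153 that resolves more boundaries in active regions, and a change of domains with transcription, both stay open and may not be separable with 1 library per line.

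The 6 libraries of DMS153 and MRC5 can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. Every other split also puts libraries of both lines into each group. The difference between the lines then widens the spread within groups and stays partly in their means, so the other splits are no reference for chance. The real split called 9612 genes and the highest other split 0, so 1 of the 10 reached the real count. For gene lists the real split called 27 and the highest other 27, reached by 3 of the 10, and for chromosome arms 12 and 11, with 1 of the 10 as high.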

How the results depend on the processing

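Alternatives chosen only after the data were seen are the run without genes of a failed status, the scaling without small RNA and mitochondrial genes, shifts without empty stretches, locus midpoints, genes called after median ratio scaling, and the estimated correlation for arms. The cause of the changes below was not tested, except where a setting itself tests fewer genes or demands less.

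No called gene reversed its direction under any scaling, filter, pseudocount or left-out library. Scaling moved the balance of higher and lower genes most. Median ratio scaling gave 4890 genes lower in DMS153 than in MRC5, and 3877 higher and 4772 lower in H209, with 2600 higher and 3680 lower in both lines. Quantile normalization gave 4242 genes higher in DMS153, 4086 higher in H209, 2464 higher in both and 9 called arms in H209. TPM scaling gave 6630 genes lower in DMS153 than in H209. Without a minimum fold the counts rose by construction, to 10711 higher and 5817 lower in DMS153, 10679 and 5159 in H209, and 6588 and 7431 between the lines. A pseudocount of 0.01 gave 6282 genes higher in both lines and 8 called lists between the lines, as did an FPKM of at least 5 with 8 lists. Without a filter 6 arms were called in DMS153 and 2 in H209. With an estimated correlation 4, 4 and 0 lists were called in DMS153, in H209 and between the lines, and 5, 0 and 5 arms.

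With each library left out in turn, genes higher and lower numbered 6385 to 6493 and 3067 to 3156 in DMS153, 5681 to 6304 and 2811 to 2859 in H209, and 2540 to 2651 and 2032 to 2587 between the lines. Genes higher in both lines numbered 4015 to 4081 and lower in both 2140 to 2186. Called lists numbered 27 to 28, 23 to 25 and 11 to 14, and called arms 11 to 12, 4 to 6 and 15 to 17. Where an H209 library is left out, the lone sample is assumed to vary like the other groups. Genes that reach 1 FPKM in H209 alone then leave the test, because 2 libraries are needed. Genes tested numbered 18203 without H209 replicate 1 and 18194 without H209 replicate 2, against 19066 in all. The list of alveolar and airway secretory markers in H209 lost its call without H209 replicate 1 (adjusted p = 0.0631) and without replicate 2 (0.0643). Cancer testis antigens between the lines had medians of -1.20 to -0.69, the latter without H209 replicate 2, where the test pointed in the other direction.

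With the replicate number as a block, 6490 genes were higher and 3125 lower in DMS153, 6292 and 2820 in H209, and 2566 and 2535 between the lines. Deviations of libraries with the same number correlated at -0.0118 to 0.124 across genes, and those with different numbers at -0.124 to 0.0541. These weak values cannot show whether the numbers carry a batch, and no pairing was used in the main fit.

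Of 117 list results 84 kept their side and direction throughout, of 123 arm results 99, and of the results of named genes 194, with 37 that changed. Mitochondrially encoded genes reversed: their median was 0.44 in H209 with quantile normalization and 0.64 in DMS153 without failed genes, which removes members. Their call in DMS153 also ended under 4 other settings, at adjusted p from 0.0682 to 0.0755. Calls in DMS153 that ended were heat shock genes (adjusted p = 0.170) and nuclear oxidative phosphorylation genes (0.140) with quantile normalization, clustered protocadherins with median ratio scaling (0.0532), and cancer testis antigens with the block (0.0515) and without small RNA (0.0903). In H209, glycolysis (0.275) and ribosomal protein genes (0.281) ended with quantile normalization, and the alveolar list at an FPKM of at least 5 (0.123). Between the lines, neuroendocrine markers (0.0746), HOXA (0.0857), HOXD (0.0639) and muscle markers (0.0639) ended with a pseudocount of 0.01, and glycolysis (0.0781), HOXC (0.0894) and protocadherins (0.0894) with TPM scaling.

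Domains of at least 100 kb had medians of 260, 320 and 320 kb in DMS153, H209 and MRC5. In the upper part of the score there were 2512, 1991 and 1850 domains with medians of 260, 340 and 320 kb and 4238, 3406 and 3161 boundaries. Shared boundaries are given in the order DMS153 near MRC5, H209 near MRC5, DMS153 near H209, MRC5 near DMS153, MRC5 near H209 and H209 near DMS153. They were 57.1%, 65.4%, 66.5%, 75.2%, 69.7% and 81.8% within 20 kb, 69.9%, 77.9%, 77.2%, 86.3%, 81.0% and 90.9% within 100 kb, and 54.8%, 62.6%, 64.0%, 72.8%, 66.9% and 79.4% in the upper part of the score. Conserved domains in the same order were 53.9%, 65.7%, 63.3%, 73.1%, 70.7% and 80% at 50% overlap and 37.1%, 45.7%, 50.05%, 50.5%, 49.1% and 63.2% at 90%.

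For genes near boundaries, the log2 odds ratio of 2 results that had passed no longer did: 0.21 for genes higher in DMS153 near gained boundaries with midpoints, and 0.27 for lower genes near shared ones within 20 kb. Others passed only under an alternative. In DMS153 these were lower genes near gained boundaries within 20 kb (-0.16), within 100 kb (-0.18), without empty stretches (-0.12) and after median ratio scaling (-0.19), higher genes near lost ones within 100 kb (-0.23), and called genes near gained ones within 100 kb (0.22) and near shared ones within 20 kb (-0.0179). In H209 these were lower genes near gained boundaries within 20 kb (-0.11), within 100 kb (-0.23) and without empty stretches (-0.0799), lower genes near lost ones within 100 kb (0.38) and near shared ones within 100 kb (0.31) and after median ratio scaling (0.35), and called genes near shared ones within 20 kb (-0.0664), with midpoints (-0.17) and without empty stretches (-0.00414). With the product of fold changes of adjacent genes, the difference between pairs without and with a boundary no longer passed. It was -0.0287 and -0.28 in DMS153 with boundaries of DMS153 and MRC5. In H209 it was -0.16 and -0.18 with boundaries of H209 and MRC5. Over all pairs this score averaged -0.72 in DMS153 and -0.63 in H209, so its sign is not read as neighbours changing in opposite directions.

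Depth limits genes under 1 FPKM, where the deposited intervals extended to either side by a median of 42.6% to 60.3% of the value.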

Other observations

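The tests in this part were planned, except the scaling without small RNA and mitochondrial genes, which was chosen after the data were seen, and the marker genes named as the highest of their list were chosen after their values were seen. Notch pathway genes were not called as a group in either carcinoma line against MRC5. In DMS153 13 of 26 were higher and 8 lower, with a relative median of 0.21 although the test pointed down (camera, adjusted p = 0.738), and in H209 12 were higher and 6 lower (adjusted p = 0.485). Of 26 apoptosis regulators, 6 were higher and 5 lower in DMS153 (adjusted p = 0.237) and 5 and 5 in H209 (adjusted p = 0.0503). In H209 the list passed as lower with pseudocounts of 0.1 (0.0469) and 0.01 (0.0445) and without a filter (0.0140). It also passed without DMS153 replicate 1 (0.0474) or 2 (0.0477), H209 replicate 2 (0.0459), or MRC5 replicate 2 (0.0410) or 3 (0.0456). BCL2L11, a proapoptotic member, stood at 32.2 ± 2.09 FPKM in DMS153 against 0.647 in MRC5, and CASP1, an inflammatory caspase, at 0.05003 FPKM against 54.5 ± 3.27. Immediate early genes were lower in both lines, with 11 of 21 lower and 2 higher in each (adjusted p = 0.00102 and 0.000786, and 0.319 and 0.291 with an estimated correlation). In DMS153 17 of 32 interferon response genes were lower and 9 higher (adjusted p = 0.00109, and 0.270 with an estimated correlation), and 7 of 13 cancer testis antigens were higher (adjusted p = 0.0386, and 0.210).

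In H209, DNA damage repair genes were higher in 24 of 30 cases (adjusted p = 0.000119, and 0.224 with an estimated correlation), chromatin architecture genes in 24 of 33 with 1 lower (0.000182, and 0.291) and Polycomb and chromatin modifiers in 23 of 37 with 2 lower (0.00413, and 0.248). Cyclin-dependent kinase inhibitors and DNA damage response targets were lower in 15 of 28 cases and higher in 5 (adjusted p = 0.000104, and 0.0686), and CDKN2A stood at 128 ± 1.13 FPKM. Cholesterol synthesis genes were higher in 19 of 24 cases (adjusted p = 0.000341, and 0.291). Ribosomal protein genes were lower in 11 of 36 cases (2.59e-08, and 0.388), unfolded protein and amino acid stress genes in 12 of 25 (1.42e-06, and 0.238) and glycolysis genes in 7 of 22 (0.00113, and 0.238). Alveolar and airway secretory markers were higher in 8 of 10 cases (adjusted p = 0.0223, and 0.238).

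Heat shock and mitochondrial genes were called as lists in DMS153 alone, and the difference between the lines was called only for nuclear oxidative phosphorylation genes. Heat shock genes were lower in 4 of 15 cases in DMS153 (adjusted p = 0.0102, and 0.332 with an estimated correlation) and in H209 2 were higher and 3 lower (0.706). Between the lines heat shock genes passed as lower in DMS153 with a pseudocount of 0.1 (0.0473), no filter (0.00818) and quantile normalization (0.0192), and without H209 replicate 1 (0.0405), H209 replicate 2 (0.0420) or MRC5 replicate 2 (0.0484). Nuclear oxidative phosphorylation genes were lower in 6 of 33 cases in DMS153 (0.000765, and 0.363), and in H209 4 were higher and 1 lower (0.374, and 0.00501 as lower with median ratio scaling). Mitochondrially encoded genes were lower in 5 of 13 cases and higher in 1 in DMS153 (0.0395, and 0.344), a result that rests on genes listed at 0 with a failed status. In H209 1 was higher (0.211), a comparison in which MT-CO1 was listed at 0 with a failed status in all MRC5 libraries. Replication-dependent histones did not pass in DMS153, with 2 of 15 higher and 4 lower (0.0792, and 0.0303 with quantile normalization), or in H209, with 9 higher and 2 lower (0.171, and 0.0136 without a filter). Between the lines mitochondrially encoded genes (0.000167) and ribosomal protein genes (0.00238) passed as lower in DMS153 with quantile normalization.

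Among developmental clusters in DMS153, 3 of 8 HOXA genes were higher (adjusted p = 0.806), 2 of 9 HOXB genes higher and 1 lower (0.806), and none of 5 HOXC genes was called (0.0742), although the list passed as lower with pseudocounts of 0.1 (0.0386) and 0.01 (0.0397) and without a filter (0.0439). In H209 5 HOXA genes were higher, 3 HOXB genes (0.844) and 4 HOXC genes (0.324, and 0.0480 without a filter). The mean and the median of HOXA in DMS153 differed in sign, at 0.81 and -0.12. Clustered protocadherins were lower in 13 of 39 cases and higher in 5 in DMS153 (0.00734, and 0.319 with an estimated correlation), and higher in 16 and lower in 9 in H209 (0.528). Ciliated cell markers were higher in 8 of 11 cases in DMS153 (0.00666, and 0.143), and higher in 7 and lower in 1 in H209 (0.195, and 0.0489 without a filter).

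Markers of other cell types ranged from low to high. Of 13 ciliated cell markers found, 11 had a mean of at least 1 FPKM in DMS153, with a median of 10.2 FPKM, and the highest, TUBB4B, a tubulin, stood at 202 FPKM in DMS153, 178 in H209 and 134 in MRC5. The highest muscle marker was TNNT1 at 113 FPKM in DMS153 and the highest tuft cell marker PTGS1, a cyclooxygenase, at 59.98 FPKM in MRC5. The highest endothelial marker was TEK at 29.7 FPKM in MRC5, the highest immune marker CD68 at 27.0 FPKM in MRC5, and the highest erythroid marker HBD at 71.4 FPKM in MRC5, while HBB was at 1.01 FPKM there. Endothelial markers had 2 of 4 tested genes higher and 2 lower in DMS153 (adjusted p = 0.528) and 1 and 2 in H209 (0.323), and immune markers 3 of 5 higher and 1 lower (0.841) and 2 and 1 (0.914). All 4 muscle markers were higher in DMS153 (0.0553) and 2 in H209 (0.297). In DMS153 the list passed with median ratio scaling (0.0194), TPM scaling (0.0122) and quantile normalization (0.0247), and without DMS153 replicate 2 (0.0448), DMS153 replicate 3 (0.0490) or MRC5 replicate 3 (0.0499). Adipocyte markers had 1 of 3 higher and 2 lower in DMS153 (0.254) and 2 lower in H209 (0.0589, with 0.0364 under TPM scaling and 0.0319 under scaling without small RNA and mitochondrial genes), and tuft cell markers 3 of 5 higher and 1 lower (0.548) and 1 lower (0.307). Alveolar and airway markers had 5 of 10 higher in DMS153 (0.0818), with MUC1 at 29.2 FPKM, and passed with pseudocounts of 0.1 (0.0491) and 0.01 (0.0322), median ratio scaling (0.0438) and TPM scaling (0.0367). The erythroid and the basal and squamous lists had 2 tested members each, too few to test, and no basal or squamous marker passed 3.90 FPKM in any library.

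Between the carcinoma lines most lineage and cell cycle lists were not called. Of 39 neuronal and synaptic genes 7 were higher and 7 lower in DMS153 (adjusted p = 0.865), of 29 epithelial markers 4 and 3 (0.824), of 48 fibroblast and matrix genes 7 and 6 (0.865), of 37 mitosis genes 6 and 2 (0.865) and of 36 DNA replication genes 1 and 6 (0.0925, with 0.0335 under TPM scaling and 0.0224 without a filter). Single genes still did: TYMS, which makes thymidylate, was lower in DMS153 with a log2 fold change of -3.60, and THY1, a surface protein of fibroblasts and neurons, stood at 0.0404 FPKM against 26.8 in H209 and 517 in MRC5. SLFN11, a DNA damage response gene, stood at 70.3 FPKM in DMS153, 24.5 in H209 and 4.85 in MRC5, and its call between the lines ended with TPM scaling (log2 fold change 0.86, with the median gene at -0.59). The other lists without a call between the lines, from DNA damage repair to tuft cell markers, had an adjusted p of 0.0576 (heat shock genes) to 0.865, among them Polycomb and chromatin modifiers, which passed as higher in DMS153 without a filter (0.0478).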
